A study of Mus musculus with 6 samples.

How the data were processed

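RNA of mouse bone marrow-derived macrophages was sequenced in 6 libraries, 1 per sample, in 4 groups: mutant untreated (2), mutant oxLDL (2), wild type untreated (1) and wild type oxLDL (1). Per the labels' protocols, marrow cells of C57BL/6 wild-type and Kindlin3-integrin mutant mice were cultured for 7 days with L929-conditioned medium and given 50 µg/ml oxLDL for 24 hours or left untreated. Libraries were made from 250 ng RNA with a stranded polyadenylated RNA kit and sequenced as 150-base paired ends. Read pairs were aligned with Bowtie2 2.1.0 and counted with RSEM 1.2.15, per the submitters' processing notes. Those notes name the human build hg19, whereas 23934 of the 24054 gene names in the table match mouse gene tables and none is written in the human style, so the build behind the counts is not given in the sources used here. No genome positions are printed for that reason.

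The authors deposited RSEM expected counts per gene, an estimate of reads per gene that may hold fractions where reads fit several genes. The authors also deposited a normalised signal per gene, made with edgeR by the trimmed mean of M-values (TMM), per the submitters' processing notes. Within each library these signal values step in whole multiples of the value of 1 read, within a tolerance of 1e-06, and the whole reads recovered from them equal the rounded expected counts for at least 99.89% of genes in each library. Differences between genes with near-identical copies depend on how RSEM divided the reads. The share of a named gene's 75-base stretches found in other genes was computed from mouse transcripts. Genes of the text with over 10% shared are given with that share and are uncertain. No share was available for some genes, among them Rn45s, Pira4, BC002163 and Btaf1.

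Expected counts were rounded to whole numbers. Of 17143 genes with any count, 12689 passed edgeR's filterByExpr and were tested with the quasi-likelihood F-test of edgeR 4.0.16 under R 4.3.3, with TMM factors computed from the counts and Benjamini-Hochberg adjustment. A model with 4 group means gave oxLDL in the mutant, genotype in untreated cells, genotype in oxLDL-treated cells and the interaction. An additive model of genotype and treatment gave genotype across treatments and oxLDL across genotypes. In these fits the single wild-type libraries are assumed to vary like the mutant pairs. A gene was called at a false discovery rate under 0.05. Levels are given as CPM, the counts scaled by library size and TMM factor, and errors of CPM are standard deviations. Errors of log2 fold changes, marked SE, are approximate. They were computed as the size of the change divided by the square root of its F statistic. oxLDL in wild type has 1 library per arm and was described by size in the main analysis, from at least 5 CPM, a log2 fold change of at least 1 and a prior count of 2.

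For a gene with 0 counts in an arm, the smallest fold change that a floor of 3 counts over that arm allows is given, which covers counting error only. For a single library this floor lay between 0.122 and 0.263 CPM. For a gene with 1 to 3 counts in an arm, levels are given.

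34 gene lists were set, and the 31 with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the p-value under a correlation estimated from the residuals beside it. The estimated setting also rests its test on the few residual degrees of freedom of these fits, so its p-values rise even without a higher correlation. For oxLDL in the mutant the integrin list had an estimated correlation of -0.0198, below the preset one. Its unadjusted camera p was 0.0132 with the preset and 0.115 with the estimated correlation. Counts of list members are given over all genes and adjusted over the list alone. The lists covered PPAR and fatty acid genes, LXR targets, SREBP2 and sterol synthesis, scavenger receptors, NRF2, ATF4, NF-kB, chemokines, interferon-stimulated genes, MHC class II presentation, alternative activation, macrophage identity, complement and phagocytosis, integrins, adhesome, actin and SRF targets, matrix and proteases, TGF-beta, lysosome, glycolysis and hypoxia, oxidative phosphorylation, mitosis and immediate early genes. They also covered markers of neutrophils, dendritic cells, fibroblasts, osteoclasts, mast cells, lymphocytes and erythroid cells, sex-linked genes, Fermt3 neighbours, genes that differ between C57BL/6 substrains or related inbred strains, and non-polyadenylated RNA. The lists, groups, models, threshold and rule for named genes were fixed before the data were examined. That rule took Fermt3 with Itgam, Itgb1, Itgb2 and Itgb3, the 10 largest changes in each direction for the 3 comparisons with most libraries, the 5 largest in each direction for the others, and up to 4 members with the smallest p from each list described. Some genes that this rule names are not reported here. The list of 51 pancreatic markers was added after the values were seen.

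Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter at 5 CPM, a 2-fold requirement, a replicate block, the mutant libraries alone, the deposited signal in limma-trend with a pseudocount of 1, and leaving out each library in turn. Chosen after seeing the data were whole reads recovered from the deposited signal, a term for the libraries with pancreatic transcripts, the replicate block in the genotype comparisons, the interaction and oxLDL in wild type, list tests without a wild-type library, the test without pancreatic markers and counts thinned to equal depth. The edgeR and camera fits of each comparison were run on simulated counts with known fold changes. For oxLDL in the mutant limma-voom, limma-trend and DESeq2 were run as well. Of 2-fold changes edgeR recovered 96% for oxLDL in the mutant, 88% for genotype across treatments and 84% for oxLDL across genotypes. It recovered 58% for genotype within either treatment and 14% for the interaction. Of 12453 genes simulated without a change, it called 25 for genotype in oxLDL-treated cells and 20 for the interaction. In the data these comparisons rest on only 61 and 62 calls. In the other comparisons it called between 11 and 20 unchanged genes. The remaining steps were not run on simulated counts. No library was left out of the reported fits.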

Results

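Bone marrow-derived macrophages of wild-type and Kindlin3-integrin mutant C57BL/6 mice were grown for 7 days in medium conditioned by L929 cells, a fibroblast line that secretes macrophage colony-stimulating factor, and were then kept for 24 hours with or without 50 µg/ml of oxidised low-density lipoprotein (oxLDL), the modified lipoprotein that loads macrophages with lipid in atherosclerosis. Kindlin-3, encoded by Fermt3, is the blood cell kindlin that binds integrin tails and activates integrins. Polyadenylated RNA was sequenced in 6 libraries, of which 2 were mutant untreated, 2 mutant oxLDL, 1 wild type untreated and 1 wild type oxLDL. Counts assigned to genes came to 11281692 and 13597908 in the mutant untreated libraries, 24273551 and 19684990 in the mutant oxLDL libraries, 21081706 in wild type untreated and 15807998 in wild type oxLDL. The replicates are not stated to come from separate animals or cultures, so p-values measure only the spread between these libraries. The mutant pairs differed by more than counting noise, with a median variance of 4.41 times (untreated) and 6.33 times (oxLDL) that of a Poisson count. Neither pair is therefore 1 library given in duplicate, but technical replicates can differ as much. Each library was counted as 1 sample, as the labels list them. Principal component 1 held 60.3% of the variance in log2 CPM and separated the 3 oxLDL libraries from the 3 untreated ones, and principal component 2 held 22.0% and separated the 2 wild-type libraries from the 4 mutant ones.

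**Figure D1:**
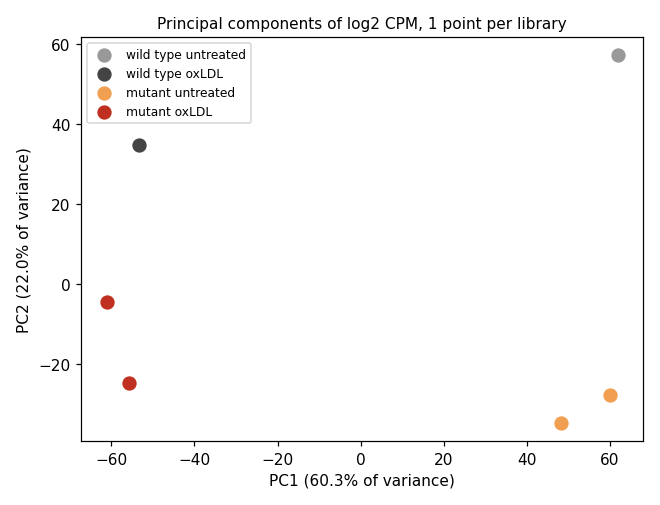
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library, coloured by genotype and treatment. The 3 oxLDL libraries lie at negative values of component 1 (60.3% of the variance) and the 2 wild-type libraries at positive values of component 2 (22.0%).

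Fermt3 was expressed in every library. Its level was 239 and 248 CPM in the mutant untreated libraries against 404 CPM in wild type untreated, and 146 and 153 CPM in the mutant oxLDL libraries against 188 CPM in wild type oxLDL. Fermt3 was lower in mutant than in wild-type untreated cells by a log2 fold change of -0.72 ± 0.11 (SE; adjusted p = 0.0264), a call that ended without mutant untreated replicate 1 (adjusted p = 0.0916) and without replicate 2. Across both treatments the change was -0.53 ± 0.11 (adjusted p = 0.0517), and among oxLDL-treated cells it was -0.33 ± 0.11 (adjusted p = 0.260). The mutant samples are titled KI, and the labels do not otherwise give the kind of mutation. The transcript level therefore cannot show whether the protein was altered.

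Of the integrin genes set for description, Itgb1 (beta 1) and Itgb2 (the leukocyte beta 2 subunit) did not pass between genotypes across treatments. Itgb1 differed by a log2 fold change of -0.11 ± 0.10 (adjusted p = 0.550) and Itgb2 by -0.46 ± 0.10 (adjusted p = 0.0616). Itgam (CD11b) measured 1103 and 1097 CPM in mutant and 2569 CPM in wild-type untreated cells, a log2 fold change of -1.21 ± 0.32 that did not pass (adjusted p = 0.0788) but passed without mutant oxLDL replicate 1 (adjusted p = 0.00333). Itgb3 (beta 3) measured 14.5 and 7.68 CPM against 0.870 CPM, a log2 fold change of 3.65 ± 0.98 (adjusted p = 0.0791), which passed without the same library (adjusted p = 0.00198). Of the sequence of Itgam, 65.2% is shared with an overlapping gene model, so its counts are uncertain.

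**Figure D2:**
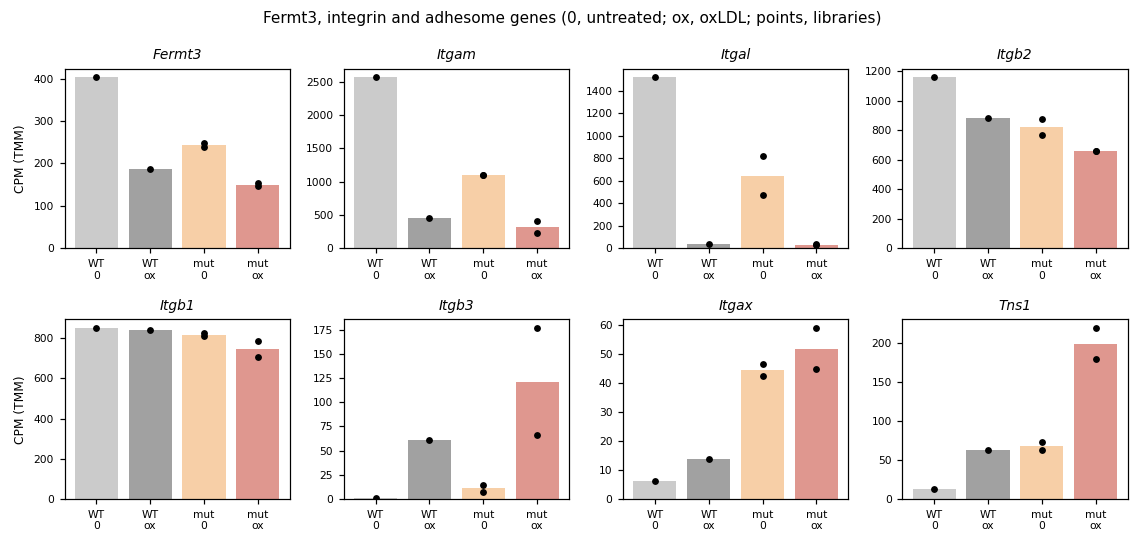
TMM-normalised CPM of Fermt3, 5 integrin genes, Itgax and the adhesome gene Tns1 in the 4 groups. Bars show group means and points the libraries (2 per mutant group and 1 per wild-type group); Fermt3 was lowest in the mutant oxLDL libraries (146 and 153 CPM).

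Transcripts of digestive enzymes of the pancreas were present in 3 of the 6 libraries. The summed level of 51 pancreatic marker genes was 222 and 176 CPM in the mutant oxLDL libraries and 296 CPM in wild type untreated, against at most 0.876 CPM in the mutant untreated and wild type oxLDL libraries. The most abundant, the amylase Amy2a5, measured 92.7, 73.4 and 123 CPM in those 3 libraries and 0 counts in the others. The lipase Pnlip, the protease genes Ctrb1 and Cela2a and the insulin gene Ins2 had the same distribution. Levels of Amy2a5 and Cela2a are uncertain, since 47.8% and 14.3% of their sequence is shared with other genes. Of 29 genes with at least 10 counts in each of the 3 libraries and at most 1 count in each other, 28 were pancreatic markers, and the highest number for any other ordered split of the libraries was 9. The list was drawn up after this distribution was seen. Because the same 3 libraries hold these transcripts, they count as higher with oxLDL in the mutant and lower with oxLDL in wild type.

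**Figure D3:**
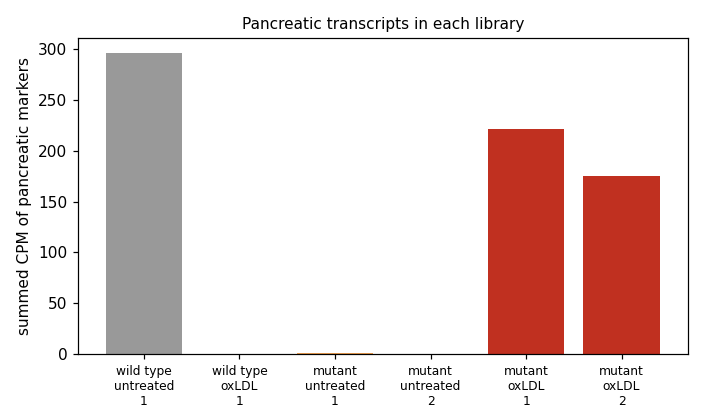
Summed CPM of 51 pancreatic marker genes in each library. The mutant oxLDL libraries hold 222 and 176 CPM and wild type untreated 296 CPM, and the other 3 libraries at most 0.876 CPM.

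The first comparison asked how oxLDL changed gene expression in mutant macrophages, the only arm with replicates on both sides. After oxLDL 39 of 39 interferon-stimulated, 39 of 40 mitotic, 21 of 24 sterol synthesis and 14 of 23 chemokine genes fell, while 31 of 37 antioxidant genes of the NRF2 programme and 22 of 36 lysosomal genes rose. These 6 lists passed with a preset correlation and had adjusted p between 0.456 and 0.616 with an estimated one. Gstm1, a glutathione transferase, rose from 44.4 ± 8.98 to 686 ± 3.39 CPM (SD, n = 2 per group), a log2 fold change of 3.94 ± 0.17 (SE; adjusted p = 0.000192). Cx3cr1, the fractalkine receptor, fell from 570.0 ± 2.75 to 4.42 ± 1.82 CPM, a log2 fold change of -7.04 ± 0.28 (adjusted p = 0.000168). Of 12689 genes tested with edgeR's quasi-likelihood test, 4515 passed a false discovery rate of 0.05, with 2090 higher and 2425 lower, and 2056 of them changed at least 2-fold (709 higher and 1347 lower). Without mutant untreated replicate 2 the count was 2626.

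All 39 measured interferon-stimulated genes fell (camera adjusted p = 2.56e-20; adjusted p = 0.456 with an estimated correlation). Ifi44 fell 16.2-fold, the helicase gene Dhx58 11.6-fold, and the oligoadenylate synthase genes Oasl2 and Oas2 15.8-fold and 14.1-fold. Cxcl10, an interferon-induced chemokine, and Iigp1, an interferon-induced GTPase, were among the 10 largest decreases, with log2 fold changes of -7.39 ± 0.54 and -7.31 ± 0.47. Of 31 NF-kB and cytokine genes 20 fell, 3 rose and 8 did not pass, or 21 fell and 4 rose adjusted over the list alone (adjusted p = 0.000127; adjusted p = 0.456 with an estimated correlation). Nfkbiz, which encodes a nuclear inhibitor of the kappa B family, fell 41.7-fold and Irg1, the itaconate synthase gene, 14.0-fold. Of 23 chemokine and chemokine receptor genes 14 fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 9.13e-05; adjusted p = 0.456 with an estimated correlation). Ccr3 fell by a log2 fold change of -7.00 ± 0.23. Among 22 immediate early genes 9 fell and 3 rose (adjusted p = 0.0164; adjusted p = 0.540 with an estimated correlation), with Fos down 19.3-fold and Zfp36, whose product destabilises cytokine mRNAs, down 4.28-fold.

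Of 37 NRF2 and oxidative stress genes 31 rose, 1 fell and 5 did not pass, or 32 and 1 adjusted over the list alone (adjusted p = 4.73e-13; adjusted p = 0.456 with an estimated correlation). Gsta3 rose 15.3-fold, the sulfiredoxin gene Srxn1 6.85-fold and the catalase gene Cat 7.23-fold. The iron exporter gene Slc40a1 rose by a log2 fold change of 4.27 ± 0.44 (adjusted p = 0.00153). Of 28 ATF4 and endoplasmic reticulum stress genes 14 rose and 6 fell, or 16 and 6 adjusted over the list alone (adjusted p = 0.0179; adjusted p = 0.540 with an estimated correlation). Atf5 rose 17.4-fold, Trib3 14.6-fold, the serine synthesis gene Phgdh 6.89-fold and the asparagine synthetase gene Asns 3.90-fold. Of 36 lysosomal genes 22 rose and 3 fell, or 23 and 3 adjusted over the list alone (adjusted p = 3.17e-05; adjusted p = 0.616 with an estimated correlation). The autophagy receptor gene Sqstm1 rose 3.95-fold and the lysosomal channel gene Mcoln1 2.36-fold. Reads of Gstm1 and Phgdh can be split with near-identical copies, since 11.7% and 35.8% of their sequence is shared.

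Of 24 SREBP2 and cholesterol synthesis genes 21 fell and none rose, or 23 and 1 adjusted over the list alone (adjusted p = 6.47e-10; adjusted p = 0.540 with an estimated correlation). Idi1 fell 10.1-fold, a log2 fold change of -3.34 ± 0.13, with 16.7% of its sequence shared with another gene. Cyp51 and the squalene epoxidase gene Sqle fell 4.74-fold and 3.74-fold. Of 24 PPAR and fatty acid genes 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.560 with an estimated correlation). The fatty acid-binding genes Fabp5 and Fabp4 rose 2.93-fold and 3.26-fold and the mitochondrial carnitine transferase gene Cpt1a 2.35-fold, while Acsl1 fell 2.01-fold. Of 19 LXR target genes 8 rose and 4 fell, and of 17 scavenger receptor genes 2 rose and 6 fell, without either list passing (adjusted p = 0.0849 and 0.0601).

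Of 40 mitotic and replication genes 39 fell and none rose, or all 40 fell adjusted over the list alone (adjusted p = 7.05e-11; adjusted p = 0.560 with an estimated correlation). The replicative helicase genes Mcm6, Mcm4 and Mcm7 fell 2.46-fold, 2.75-fold and 3.74-fold. Of 28 complement and phagocytosis genes 13 fell and 5 rose, or 15 and 7 adjusted over the list alone (adjusted p = 0.0207; adjusted p = 0.540 with an estimated correlation), and this list did not pass without mutant untreated replicate 1 (adjusted p = 0.0542). C1qa fell 9.23-fold and C5ar1, the receptor of C5a, 8.50-fold. Of 14 MHC class II presentation genes 5 fell and none rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.0157; adjusted p = 0.616 with an estimated correlation), with Cd74 down 3.76-fold, and without the same library the list gave an adjusted p of 0.0576. Of 17 alternative activation genes 4 fell and 1 rose, or 4 and none adjusted over the list alone (adjusted p = 0.0423; adjusted p = 0.540 with an estimated correlation), with Fcrls down 8.85-fold. That call ended without mutant oxLDL replicate 2 (adjusted p = 0.139).

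Of 19 integrin genes 8 fell and 1 rose (adjusted p = 0.0272; adjusted p = 0.456 with an estimated correlation). Itgal (CD11a) fell by a log2 fold change of -4.35 ± 0.34 (adjusted p = 0.000654), Itga9 by -3.34 ± 0.20 and Itgam by -1.81 ± 0.28, while Itgb3 rose by 3.45 ± 0.55 (adjusted p = 0.00581). Fermt3 itself fell by -0.71 ± 0.089 (adjusted p = 0.00267). Of 53 adhesome genes 24 fell and 5 rose, or 25 and 5 adjusted over the list alone (adjusted p = 0.0136; adjusted p = 0.456 with an estimated correlation), with the Src family kinase gene Lyn down 3.41-fold (10.1% of its sequence shared). Of 33 actin and SRF target genes 20 fell and 3 rose, or 21 and 3 adjusted over the list alone (adjusted p = 0.000604; adjusted p = 0.456 with an estimated correlation), with Actb down 4.11-fold and the actin regulator gene Coro1a down by a log2 fold change of -2.00 ± 0.12. Of 25 TGF-beta genes 7 fell and 3 rose (adjusted p = 0.0440; adjusted p = 0.456 with an estimated correlation), with Tgfbi down 8.72-fold. The TGF-beta call ended without mutant oxLDL replicate 1 (adjusted p = 0.0531) or mutant untreated replicate 1 (0.0866).

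By the fixed rule on size, 8 of the 10 largest increases in mutant cells were the pancreatic genes Amy2a5, Pnlip, Ctrb1, Ins2, Cela2a, Cel, Cpa1 and Cpb1, which were at least 709-fold (Amy2a5) to at least 61.2-fold (Cpa1) higher against a floor of 3 counts over the untreated pair, Cpb1 having 1 count there. The others were Pira4, at 13.4 and 47.3 CPM with oxLDL and 0 counts without, and Dlg2, which encodes a synaptic scaffold protein and rose 38.8-fold. Pira4 was not found among the reference transcripts, so its shared sequence is unknown. Among the next genes once pancreatic markers were left out, a step chosen after their values were seen, the coagulation factor gene F5 rose 24.8-fold. The largest decreases included Cd207 (langerin), at 15.4 and 19.7 CPM in untreated and 0 counts in oxLDL-treated mutant cells, at least 262-fold lower. Nhs measured 1.66 and 16.1 CPM and Gfi1b 3.59 and 7.25 CPM in untreated mutant cells, and both had 0 counts with oxLDL. Nox1, an NADPH oxidase gene, fell 178-fold and Ch25h, the cholesterol 25-hydroxylase gene, 136-fold. Serpina3g measured 5.52 and 13.0 CPM untreated against 0.0408 and 0 CPM, and Spib 4.73 and 25.6 against 0 and 0.0993 CPM.

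The remaining lists set for mutant cells did not pass, except 1. Of 16 genes known to differ between C57BL/6 substrains or related inbred strains 9 fell and 2 rose (adjusted p = 0.0413; adjusted p = 0.456 with an estimated correlation, and 0.0711 without mutant untreated replicate 1). Those that moved include immune genes, namely Casp4, an inflammatory caspase gene down 2.29-fold, and Klra2, a lectin-like receptor gene down 7.78-fold, while Ide, which encodes an insulin-degrading protease, rose 1.72-fold. Not passing were extracellular matrix and proteases (0.0849), glycolysis and hypoxia (0.154), oxidative phosphorylation (0.876), macrophage identity (0.368), Fermt3 neighbours on its chromosome (0.890) and non-polyadenylated RNA (0.865), each value being the camera adjusted p. Rn45s, a precursor of ribosomal RNA and a member of the last list, moved with treatment, at 2492 and 1836 CPM in mutant oxLDL and 1555 CPM in wild type oxLDL against 1194, 1307 and 1133 CPM in the untreated libraries. It was named after its values were seen, with a log2 fold change of 0.78 ± 0.18 in the mutant (adjusted p = 0.0217, and up to 0.0970 with 1 library left out). Markers of neutrophils (0.368), dendritic cells (0.380), fibroblasts (0.974), osteoclasts (0.919) and lymphocytes (0.919) did not pass either. Mast cell and erythroid markers had 3 measured genes each and sex-linked genes 1 (Xist, present in all 6 libraries), too few for the list test. Median and mean differed in sign for the fibroblast list (-0.88 against 0.50, the test pointing up), for the oxidative phosphorylation and lymphocyte lists, for mast cell and erythroid markers and for the Fermt3 neighbours.

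**Figure D4:**
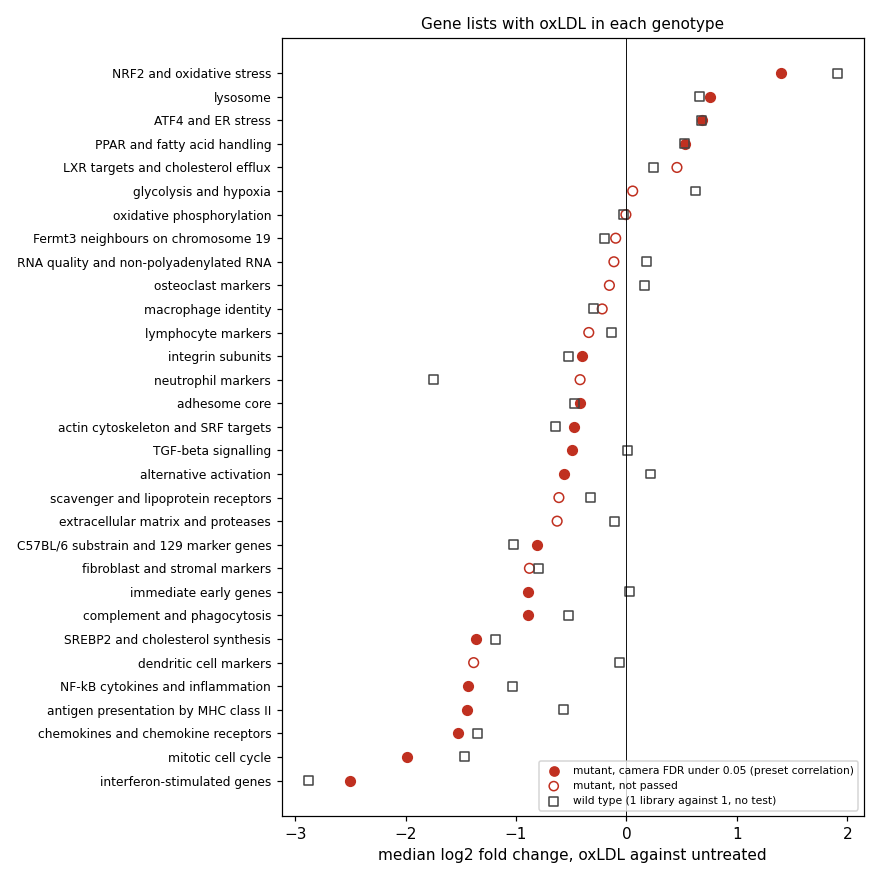
Median log2 fold change of each gene list with oxLDL against untreated, in mutant cells (circles, filled where camera with its preset correlation gave an adjusted p under 0.05) and in wild-type cells (squares, 1 library against 1). NRF2 genes have medians of 1.40 in the mutant and 1.91 in wild type, and interferon-stimulated genes -2.51 and -2.88.

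In wild-type cells the same question rests on 1 library against 1, so there is no replicate check, and changes are described by size without a p-value. Itgb3 measured 60.9 CPM with oxLDL and 0.870 CPM without, and the cystine transporter gene Slc7a11 189.7 and 2.92 CPM. Gsta3 measured 83.1 and 0.614 CPM, the cell cycle inhibitor gene Cdkn1c 208 and 1.89 CPM, and Serpinb9b 25.4 and 0.358 CPM. On the lower side Slc13a3, a dicarboxylate transporter gene, measured 14.5 CPM with oxLDL and 2799 CPM without, Raver2 0.576 and 175 CPM, Rasgrp1 0.128 and 64.3 CPM, and Ch25h was at least 139-fold lower. Amy2a5, a pancreatic gene, was at least 642-fold lower. Of 9840 genes with at least 5 CPM in either library, 1926 differed at least 2-fold, with 779 higher and 1147 lower, 13 of them pancreatic markers. In an alternative test that assumes these single libraries vary like the mutant pairs, 2946 genes passed.

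The gene lists of wild-type cells were placed among 10000 random lists matched on mean expression, as a description of these 2 libraries. The median log2 fold change of NRF2 genes was 1.91 with 1 gene at its bound, and 29 of 37 were at least 2-fold higher. Their fitted median lay above 100% of the random lists. Interferon-stimulated genes had a median of -2.88, with 38 of 39 at least 2-fold lower, mitotic genes -1.47, with 29 of 40 lower, and sterol synthesis genes -1.19, with 15 of 24 lower, each below all the random lists. Lysosomal genes had a median of 0.67, ATF4 genes 0.68 and glycolysis and hypoxia genes 0.62, all above 100% of the random lists. Neutrophil markers had a median of -1.75, at percentile 0.110. Over the 4515 genes that passed in the mutant, 4247 (94.1%) had a change of the same sign in wild type. Over all tested genes, which are not independent replicates, 77.3% had the same sign, and the log2 fold changes of the genotypes had a Pearson correlation of 0.692 and a Spearman correlation of 0.722.

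With both genotypes in 1 additive model, 5134 genes passed for oxLDL, 2419 higher and 2715 lower. NRF2 genes rose in 32 of 37 cases (adjusted p = 1.42e-12; adjusted p = 0.396 with an estimated correlation), and all 39 interferon-stimulated genes fell (adjusted p = 2.89e-22; adjusted p = 0.396 with an estimated correlation). Of the lists, 14 passed and 0 with an estimated correlation, and the integrin list was not among them (adjusted p = 0.0509). The largest increases by the fixed rule included Dlg2 (36.3-fold), Cdkn1c (28.8-fold), the pseudogene Atp6v0c-ps2 and Gsta3 (24.2-fold), followed by the glycine transporter gene Slc6a9, the deiodinase gene Dio2, Slc7a11, Rab15 and Slc40a1, all between 20.2-fold and 22.3-fold. Of the Atp6v0c-ps2 sequence, 80.8% is shared with other genes. The largest decreases were Cd207, at least 245-fold with the genotypes pooled, and Gfi1b, at 6.14 CPM in wild type untreated and 0 counts in the 3 oxLDL libraries. Next came Nhs, Spib, Ch25h (199.6-fold), Cxcl10, Sema7a, Serpina3g, Iigp1 (158-fold) and Nox1 (134-fold). The bound of Cd207 comes mostly from the mutant, with a mean of 17.6 CPM in mutant untreated. In wild type untreated Cd207 measured 1.48 CPM, against a floor of 0.192 CPM in wild type oxLDL. Itgb2 fell by a log2 fold change of -0.35 ± 0.098 (adjusted p = 0.0295), a call that ended when any 1 library other than mutant untreated replicate 1 was left out (up to adjusted p = 0.111).

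**Figure D5:**
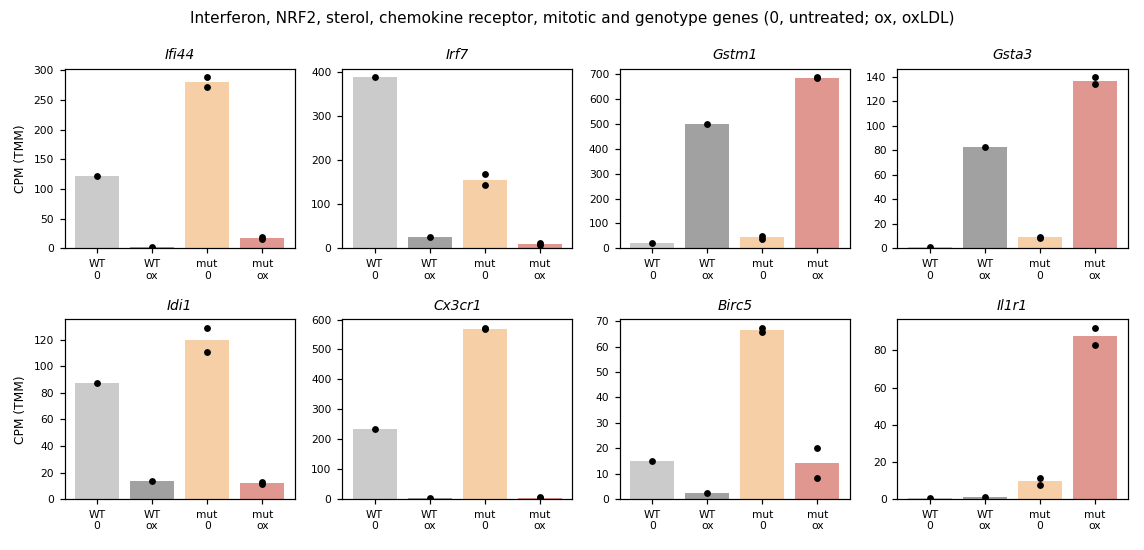
TMM-normalised CPM of interferon genes (Ifi44, Irf7), NRF2 genes (Gstm1, Gsta3), a sterol synthesis gene (Idi1), Cx3cr1, the mitotic gene Birc5 and Il1r1 in the 4 groups. Bars are group means and points libraries; Gstm1 lies between 501 and 689 CPM in the 3 oxLDL libraries and at most 50.7 CPM in the untreated ones.

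The genotype comparison across treatments asked how mutant macrophages (4 libraries) differed from wild-type ones (2) within each treatment. Both wild-type libraries carry the replicate number 1 and may come from 1 animal or culture. Without either of them, only 1 treatment keeps both genotypes, and the additive fit then gives the genotype contrast of that treatment. A call changed there shows what that treatment gave alone, not how the pooled call depends on 1 library. Il1r1, the interleukin-1 receptor gene, was 48.9-fold higher in the mutant, a log2 fold change of 5.61 ± 0.50 (SE; adjusted p = 0.00986), with 11.4 and 7.53 against 0.563 CPM in untreated and 92.1 and 82.9 against 1.02 CPM in oxLDL-treated cells. C1qa, a subunit of complement C1q, was lower by -1.89 ± 0.16 (adjusted p = 0.00943) and the surface antigen gene Ly6a by -3.25 ± 0.22 (adjusted p = 0.00673). Of 40 mitotic genes 18 were higher in the mutant, and of 39 interferon-stimulated genes 5 were lower and 1 higher, both lists having an adjusted p = 0.734 with an estimated correlation. In all 514 genes passed, 322 higher and 192 lower, and 319 differed at least 2-fold (267 higher and 52 lower). The count depends on single libraries: it was 8 without mutant untreated replicate 2, 35 without mutant untreated replicate 1 and 217 without mutant oxLDL replicate 1. Of the 39 named genes called here, Ly6a and C1qa kept their call whichever library was left out, and Il1r1 lost it without mutant untreated replicate 2 (adjusted p = 0.0643).

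Of 40 mitotic and replication genes 18 were higher in the mutant and none lower, or 34 adjusted over the list alone (camera adjusted p = 7.44e-15; adjusted p = 0.734 with an estimated correlation). Birc5 (survivin) was 4.92-fold higher, the cyclin gene Ccnb2 4.90-fold, Cdc20 4.47-fold and Ccne2 2.71-fold, and each of these 4 calls ended without the wild type untreated library (adjusted p between 0.151 and 0.165). Of 39 interferon-stimulated genes 5 were lower and 1 higher, or 15 and 3 adjusted over the list alone (adjusted p = 0.00014; adjusted p = 0.734 with an estimated correlation). Irf7 was lower by a log2 fold change of -1.38 ± 0.13 (adjusted p = 0.0122, and 0.0863 without mutant untreated replicate 2) and the RNA sensor gene Ifih1 1.51-fold lower. The related gene Ifi44l went the other way, with 0 counts in both wild-type libraries and 26.9 and 37.5 CPM in mutant untreated and 1.47 and 4.62 CPM in mutant oxLDL cells (adjusted p = 0.164 without wild type untreated). Of 33 actin and SRF target genes none passed over all genes and 12 were lower adjusted over the list alone (adjusted p = 0.000484; adjusted p = 0.734 with an estimated correlation), with log2 fold changes of -1.16 ± 0.25 for Cnn2 and -0.51 ± 0.13 for the profilin gene Pfn1. Both genes passed in the fit without wild type oxLDL, which compares the genotypes in untreated cells alone. Of 34 matrix and protease genes 2 were higher (adjusted p = 0.0234; adjusted p = 0.734 with an estimated correlation, 0.0761 without mutant untreated replicate 2 and 0.281 without wild type untreated), namely the membrane metalloprotease gene Mmp14 (2.30-fold) and the tenascin gene Tnc (13.0-fold). Both calls ended without wild type untreated (adjusted p = 0.108 and 0.331).

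Among adhesion genes the dendritic cell and macrophage integrin Itgax (CD11c) was 5.09-fold higher in the mutant (adjusted p = 0.0163) and Itga9 1.99-fold lower (adjusted p = 0.0328). Itgad had 0 counts in both wild-type libraries and was at least 14.5-fold higher. Of the 19 integrin genes 2 were higher and 1 lower, or 3 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.731). Of 53 adhesome genes 3 were higher and 3 lower, or 7 and 14 adjusted over the list alone (adjusted p = 0.321). The focal adhesion gene Tns1 (tensin 1) was higher by a log2 fold change of 2.03 ± 0.21 and Src by 1.35 ± 0.23, while Apbb1ip, whose product RIAM links Rap1 to talin, was lower by -0.86 ± 0.14. Without mutant untreated replicate 2 the adjusted p was 0.0887 for Itgax and for Tns1 and 0.118 for Itgad, and without wild type untreated it was 0.190 for Itga9, 0.158 for Src and 0.167 for Apbb1ip. Of 24 genes that neighbour Fermt3 none passed over all genes or adjusted over the list alone (camera adjusted p = 0.338).

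The other named genes of this comparison were Elavl4, with 15.8 ± 5.96 CPM (SD, n = 2) in mutant untreated cells and 2 counts over both wild-type libraries, the engulfment receptor gene Megf10 (83.1-fold higher), Igsf3, Eltd1, Dock3, Akap2 and Angptl7 (between 19.5-fold and 33.3-fold higher) and the lectin gene Cd209c (17.6-fold higher). Lower were Rab6b (11.4-fold), Cd38, Fcrl5, the chemerin receptor gene Cmklr1 and Mfng (between 3.65-fold and 3.93-fold). All of these lost their call without mutant untreated replicate 2. Ndufs5, a subunit gene of respiratory complex I, measured 19.97 and 18.1 CPM in wild type and at most 0.448 CPM in the mutant libraries, with 15.7% of its sequence shared with other genes, and Akap2 shares 82.2%. The gene that shares sequence with Ndufs5, BC002163, was higher in the mutant while their sum was nearly equal, as described under other observations. Of 12 neutrophil markers 3 were lower across treatments and none higher (adjusted p = 0.0216; adjusted p = 0.734 with an estimated correlation and 0.501 without wild type untreated), with a median log2 fold change of -2.41 in untreated and -0.28 in oxLDL-treated cells. In the latter 1 of 12 was lower and the list did not pass (adjusted p = 0.326), and 3 of 12 had 0 counts in an arm there. The granule gene Ngp measured 12.5 CPM in wild type untreated and 0.128 CPM in wild type oxLDL, and 1 count over the 4 mutant libraries. S100a9 measured 9.93 and 0.0640 CPM and 3 counts. Padi4 measured 7.88 and 16.3 CPM in wild type against 0.526 to 1.64 CPM in the mutant. The neutrophil calls ended without mutant untreated replicate 2 (adjusted p = 0.0643 for Padi4). Of 3 mast cell and basophil markers, too few for the list test, 1 was higher across treatments, or 2 adjusted over the list alone (median 2.36). In untreated cells none passed over all genes and 2 were higher adjusted over the list alone (median 4.14), and in oxLDL-treated cells none and 1 (median 1.10). The marker called across treatments was Kit, named after its values were seen, with a log2 fold change of 3.06 ± 0.61 (adjusted p = 0.0484, and up to 0.179 with 1 library left out). It measured 4.91 and 2.61 against 0.205 CPM in untreated and at least 24.2 against 6.60 CPM in oxLDL-treated cells.

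In untreated cells alone, 10 of 34 matrix and protease genes and 13 of 40 mitotic genes were higher in the mutant than in the single wild-type library, both lists having an adjusted p = 0.754 with an estimated correlation. Plau, the urokinase gene, was 6.88-fold higher in the mutant (173 ± 2.46 CPM, SD, n = 2, against 25.3 CPM; adjusted p = 0.00398) and Col18a1 5.82-fold higher (adjusted p = 0.0128). Itgax was 7.25-fold higher, Tns1 5.51-fold and Fos 2.86-fold, and these 5 calls held whichever mutant library was left out. In all 896 genes passed, 538 higher and 358 lower, 24 of the lower being pancreatic markers, which the wild type untreated library holds, and 545 differed at least 2-fold (424 higher and 121 lower). Leaving out mutant untreated replicate 1 gave 80 and replicate 2 gave 317, and leaving out mutant oxLDL replicate 1 or 2 gave 1822 or 1626.

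Of 34 matrix and protease genes 10 were higher and none lower, or 10 and 1 adjusted over the list alone, with a median log2 fold change of 0.97 (adjusted p = 0.00261; adjusted p = 0.754 with an estimated correlation). Of 40 mitotic genes 13 were higher and none lower, or 37 adjusted over the list alone (adjusted p = 1.98e-12; adjusted p = 0.754 with an estimated correlation), Mcm6 2.01-fold and Cdt1 2.02-fold. Of 39 interferon-stimulated genes 4 were lower and 2 higher, or 12 and 2 adjusted over the list alone (adjusted p = 0.000713; adjusted p = 0.754 with an estimated correlation), with Irf7 lower 2.48-fold and Ifi44 higher 2.32-fold. Of 24 sterol synthesis genes 3 were higher, or 4 adjusted over the list alone (adjusted p = 0.0192; adjusted p = 0.754 with an estimated correlation, and 0.0981 without mutant untreated replicate 1), Sqle 1.65-fold. Of 33 actin genes 3 were lower and 2 higher, or 11 and 3 adjusted over the list alone (adjusted p = 0.0147; adjusted p = 0.754 with an estimated correlation), with Coro1a lower 1.89-fold and the vimentin gene Vim higher 2.44-fold. Of 22 immediate early genes 3 were higher, or 6 with 1 lower adjusted over the list alone (adjusted p = 0.0472; adjusted p = 0.754 with an estimated correlation), and this list did not pass without mutant untreated replicate 1 (0.120), mutant oxLDL replicate 1 (0.0549) or mutant oxLDL replicate 2 (0.0607). Neutrophil markers were lower in 5 of 12 cases, or 6 adjusted over the list alone (median -2.41; adjusted p = 9.26e-05; adjusted p = 0.754 with an estimated correlation). The lactoferrin gene Ltf had 0 counts in the mutant pair and 8.29 CPM in wild type, at least 70.8-fold lower. Without mutant untreated replicate 1 the named calls of this paragraph ended (adjusted p between 0.0562 for Cnn2, 2.91-fold lower, and 0.114 for Sqle).

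By size, the 5 largest named increases in untreated mutant cells were Ifi44l (at least 209-fold), Elavl4 and Igsf3 (2 wild-type counts each), Megf10 (81.7-fold) and the amino acid transporter gene Slc36a2 (51.7-fold). All 5 lost their call without mutant untreated replicate 1 (adjusted p between 0.0542 and 0.105). The 5 largest decreases were the pancreatic genes Amy2a5 (at least 1052-fold), Pnlip, Ctrb1, Cela2a and Ins2. Among adhesome genes 6 were higher and 10 lower, or 10 and 17 adjusted over the list alone, and the list did not pass (adjusted p = 0.316), with Src 3.46-fold higher and the GTPase gene Rap1b 1.81-fold lower (adjusted p = 0.0905 and 0.0909 without mutant untreated replicate 1).

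In oxLDL-treated cells the genotypes differed in fewer genes past the threshold. C5ar1 was 6.47-fold lower in the mutant (24.0 ± 3.36 CPM, SD, n = 2, against 155 CPM; adjusted p = 0.00949), Il1r1 84.7-fold higher (adjusted p = 0.00949) and the cationic amino acid transporter gene Slc7a2 15.1-fold higher (adjusted p = 0.00949), and these 3 calls held whichever mutant library was left out. In all 61 genes passed, 38 higher and 23 lower, 11 of the higher being pancreatic markers, such as Amy2a5 (at least 432-fold), Pnlip, Ctrb1, Ins2 and Cela2a, of which the last 4 lost their call without mutant untreated replicate 1. Without the pancreatic markers in the test 29 genes passed, and limma-voom called 11 genes, 3 higher and 8 lower, with no pancreatic marker among them. Leaving out mutant untreated replicate 1 or 2 gave 5 or 30 genes, and leaving out mutant oxLDL replicate 1 or 2 gave 218 or 473. Other named genes were Dlg2 (9.25-fold higher), Gdpd3 and Ank2 on the higher side, and Ndufs5, Padi4 (12.8-fold), Nes (nestin, 6.68-fold) and Dynlt1f on the lower side, all of which lost their call without mutant untreated replicate 1 (adjusted p up to 0.108). Il1r1, Slc7a2, Dlg2, Gdpd3 and Ank2 were named here after values were seen, as the next once pancreatic markers were left out. Of the Dynlt1f sequence 83.3% is shared with other genes.

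Mitotic genes had a median log2 fold change of 1.35 in oxLDL-treated mutant cells (adjusted p = 1.37e-06; adjusted p = 0.828 with an estimated correlation), although none of 40 passed over all genes, and 18 were higher and 1 lower adjusted over the list alone. NRF2 genes had a median of -0.47 (adjusted p = 2.03e-06; adjusted p = 0.828 with an estimated correlation), and 1 of 37 passed, or 14 lower and 1 higher adjusted over the list alone. That gene was Procr, the endothelial protein C receptor gene, lower by a log2 fold change of -1.32 ± 0.13 (adjusted p = 0.0293, and 0.0598 without mutant untreated replicate 1). Lists of actin (adjusted p = 0.000525), immediate early (0.00924), interferon (0.0101) and glycolysis genes (0.0194) were lower and fibroblast markers higher (0.0141, median 1.86, or 0.76 with 2 genes at their bound), each with an adjusted p = 0.828 with an estimated correlation. Of their members, 1 of 22 immediate early genes was lower, or 6 adjusted over the list alone, and 1 of 39 interferon genes was higher, or 1 higher and 5 lower adjusted over the list alone. None of the actin, glycolysis and fibroblast genes passed either way. The immediate early gene Dusp1, a phosphatase gene, was 2.36-fold lower and Ifi44 6.16-fold higher. The interferon call ended without mutant oxLDL replicate 2 (0.0917), the glycolysis call without mutant oxLDL replicate 1 (0.0516) or 2 (0.0707) and the fibroblast call without mutant oxLDL replicate 1 (0.0516). Without mutant untreated replicate 1 the adjusted p was 0.104 for Dusp1 and 0.0549 for Ifi44.

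The interaction tested whether the response to oxLDL differed between genotypes. It is the log2 fold change with oxLDL in the mutant minus that in wild type, and its sign does not give the strength of a response. A gene that fell more in the mutant, such as Fos, counts as having a lower response there. A gene that fell less in the mutant, such as Herpud1, counts as having a higher one. In simulated counts the interaction test recovered 14% of 2-fold differences, so genes that did not pass are not shown to respond equally. It also called 20 genes simulated without a difference. Of 37 NRF2 genes 2 and of 22 immediate early genes 2 passed with a lower response in the mutant, both lists having an adjusted p = 0.745 with an estimated correlation. Procr measured 11.5 and 13.2 CPM in mutant untreated and 51.2 and 47.8 CPM in mutant oxLDL cells, and 4.45 CPM without and 124 CPM with oxLDL in wild type, an interaction of -2.81 ± 0.21 (SE; adjusted p = 0.0140). Fos gave -2.28 ± 0.22 (adjusted p = 0.0207), with 166 and 200.5 CPM in mutant untreated, 64.5 in wild type untreated and 9.54 to 16.3 CPM in the oxLDL libraries. Sdc1, the syndecan-1 gene, fell from 62.4 ± 19.2 to 16.8 ± 0.693 CPM in the mutant and measured 3.94 and 19.2 CPM in wild type without and with oxLDL (adjusted p = 0.0236). In all 62 genes passed, 24 with a higher and 38 with a lower response in the mutant, and 19 of the former were pancreatic markers. This contrast has the same sign pattern as the distribution of the pancreatic transcripts, so the interaction and that split of the libraries are the same contrast.

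Procr, Fos and Sdc1 kept their call whichever mutant library was left out. Plau (log2 -2.13 ± 0.18) and Col18a1 (-3.30 ± 0.34) lost it without mutant untreated replicate 1 or 2 (adjusted p up to 0.0598 and 0.0612), and the elastase gene Mmp12 (-2.67 ± 0.30) and Gsta3 (-3.13 ± 0.26) without replicate 1 (adjusted p = 0.0501 and 0.0501). Serpinb9b (-3.51 ± 0.40) and Gprc5b (-3.47 ± 0.43) lost it without either (up to 0.134 and 0.103). The 5 largest higher responses were the pancreatic genes Amy2a5, Pnlip, Ctrb1, Ins2 and Cela2a. Next, chosen after values were seen, were Cela1, Il16 (2.33 ± 0.19), the endoplasmic reticulum stress gene Herpud1 (2.18 ± 0.18) and Rilpl2 (1.37 ± 0.16), all lost without mutant untreated replicate 1 (adjusted p between 0.0515 and 0.129). Cela1, an elastase gene that is not among the 51 markers, measured 10.7, 9.04 and 14.1 CPM in the 3 libraries with pancreatic transcripts and 3.07, 3.38 and 1.79 CPM in the others. The number of calls was 23 with the pancreatic markers left out of the test, 19 and 25 without mutant untreated replicates 1 and 2 and 246 without mutant oxLDL replicate 1. Itgb3 did not pass (log2 -2.66 ± 1.17, adjusted p = 0.474) but passed without mutant oxLDL replicate 1 (0.0245).

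By list, 2 of 37 NRF2 genes had a lower response, or 14 adjusted over the list alone (adjusted p = 4.31e-08; adjusted p = 0.745 with an estimated correlation). Of 22 immediate early genes 2 had a lower response, or 6 adjusted over the list alone (adjusted p = 1.41e-05; adjusted p = 0.745 with an estimated correlation), Dusp1 by -2.19 ± 0.20 (0.109 without mutant untreated replicate 1). Glycolysis genes had a lower response in none of 32 over all genes and 6 adjusted over the list alone (adjusted p = 0.000746), and mitotic genes 1 and 3 of 40 (adjusted p = 0.00078), the latter list losing its call without mutant oxLDL replicate 2 (0.843). Pcna, the mitotic list member that passed and shares 13.8% of its sequence, gave -1.61 ± 0.19 (0.132 without mutant untreated replicate 1). Chemokine genes had none of 23, or 1 adjusted over the list alone (adjusted p = 0.0136) and matrix genes 3 of 34, or 7 lower and 2 higher adjusted over the list alone (adjusted p = 0.0255, and 0.0548 without mutant untreated replicate 2), the matrix list having a negative median, a positive mean and a test pointing down. The neutrophil list test pointed to a higher response in the mutant (adjusted p = 0.000154) with none of 12 passing, Ngp and S100a9 having their highest level in wild type untreated. For these 5 lists the adjusted p was 0.745 with an estimated correlation.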

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

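All explanations weighed in this part were chosen after the results were seen. The test of a differing response to oxLDL between mutant and wild-type cells passed for 62 genes, and such a difference between groups is what marked each result of this part. Among lists, the adjusted p of the interaction was 4.31e-08 for NRF2 genes, 1.41e-05 for immediate early genes, 0.000154 for neutrophil markers, 0.000746 for glycolysis and hypoxia genes, 0.000780 for mitotic genes, 0.0136 for chemokine genes and 0.0255 for matrix and protease genes, each at a preset correlation and each 0.745 with an estimated one. Among genes, edgeR's adjusted p was 0.00432 for Amy2a5 and 0.0140 for Pnlip, Ctrb1, Ins2, Cela2a, Cela1, Il16, Herpud1 and Gsta3. It was 0.0236 for Sdc1, 0.0282 for Col18a1, 0.0359 for Serpinb9b, 0.0401 for Rilpl2 and 0.0463 for Gprc5b.

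Pancreatic transcripts in 3 libraries could come from RNA or reads of another sample, from the macrophages or from unequal depth. Over markers with at least 10 counts in each of the 3 libraries, the lowest correlation of log2 CPM between libraries was 0.977, which fits pancreatic RNA or reads in these libraries but does not tell 1 source from several. A response to oxLDL would raise the markers in wild type too, but the wild type oxLDL library held 0.13% of the level of wild type untreated. Depth does not account for the absence, since the shallowest library would hold 2004 marker reads at the lowest level of the 3 libraries and held 10. The step at which the transcripts entered was not tested.

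The calls of the oxLDL comparison in the mutant and of the interaction could come from the split of the libraries that the pancreatic transcripts mark. For oxLDL in the mutant the split runs the other way in wild type, and 94.1% of the calls had the same sign there, against 77.3% of all tested genes. That is not what such a split would give for the calls as a set. It does not exclude the split for single calls, and 29 of the 4515 calls were pancreatic markers. For the interaction, 43 of the 62 calls were not among the listed pancreatic markers, Cela1 being 1 of them, and the split and the interaction are the same contrast, so they cannot be told apart with these libraries. If unequal depth were the cause, the interaction calls would be lost once depth is equal. With all libraries thinned to the shallowest, 80.6% (50 of 62) passed in the same direction. The libraries with pancreatic transcripts are also the deepest, so depth follows the same split, and thinning tests only the number of reads.

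The genotype calls may come from the same split, from genes carried along with the mutated gene or from the wild-type source. That source is 1 library per treatment, and both share the replicate number 1, so it may be 1 animal or culture. Of the 872 untreated calls that were not pancreatic markers, 722 (82.8%) had the same sign in the oxLDL libraries, where the split is turned around. These genes were selected by their call. Over all tested genes, the genotype differences in untreated and oxLDL-treated cells had a Pearson correlation of only 0.341 and a Spearman correlation of 0.405. Of the calls across treatments, 1.17% (6 of 514) lay among the 200 nearest tested neighbours of Fermt3, where 8.10 would lie by chance. With 1 wild-type library per treatment, a property of the wild-type source and an effect of the genotype are the same contrast and cannot be told apart. A biological explanation other than genotype and oxLDL was not tested. A difference in strain background, raised below for Ndufs5, was not tested for these calls either.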

How the results depend on the processing

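The fit with the pancreatic split, the tests without pancreatic markers, the recovered reads and the thinned counts were chosen after seeing the data; the cause was not tested for any change below except where fewer libraries or genes entered. Calls that also changed at least 2-fold numbered 2056 of 4515 for oxLDL in the mutant, 2178 of 5134 for oxLDL across genotypes, 319 of 514 for genotype across treatments and 545 of 896 for genotype in untreated cells. With the DESeq2 Wald test the counts were 1513 for genotype across treatments, 391 for genotype in oxLDL-treated cells (61 in edgeR) and 221 for the interaction (62 in edgeR), and limma-voom gave 11 for genotype in oxLDL-treated cells (3 higher and 8 lower, against 38 and 23). Without a count filter they were 1387 across treatments, 2435 in untreated cells, 974 in oxLDL-treated cells and 546 for the interaction. Leaving the pancreatic markers out gave 29 and 23 for the last 2, and a term for the split of libraries gave 1181 for genotype across treatments. That term is the interaction, so this fit gives the genotype effect averaged over the treatments. It is not a correction for the pancreatic transcripts. For oxLDL in wild type, 2946 genes passed with the spread of the mutant pairs, against 1926 by size. Of 58 list calls, 0 remained with an estimated correlation. That setting also leaves the test few residual degrees of freedom, so the loss does not tell correlated genes from the small number of libraries.

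With 1 library left out at a time, counts ranged from 2626 to 4057 for oxLDL in the mutant, from 3480 to 4529 for oxLDL across genotypes, from 8 to 877 for genotype across treatments, from 80 to 1822 for genotype in untreated cells, from 5 to 473 for genotype in oxLDL-treated cells, from 19 to 246 for the interaction and from 53 to 64 for list calls. Wild-type libraries were left out only in the comparisons across treatments and across genotypes, for lists in a step chosen after seeing the data. Such a fit repeats the contrast within the treatment or genotype that keeps both sides. The highest gene counts of both comparisons come from such fits. A lone library left in an arm is assumed to vary like the others. Of 340 named results, 154 kept their side of the threshold everywhere, 121 lost a call and 64 gained one somewhere. The interaction of Itgb2, 0.06 and not called, ranged from -0.0048 without mutant untreated replicate 1 to 0.16 without mutant untreated replicate 2.

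The replicate number as a block gave 5089 calls for oxLDL in the mutant and 4765 for oxLDL across genotypes. In fits chosen after seeing the data, with 1 or 2 residual degrees of freedom, it gave 344 for genotype across treatments, 1870 in untreated cells, 462 in oxLDL-treated cells, 162 for the interaction and, with the spread of the mutant pairs, 3626 for oxLDL in wild type. Of the lists 17 passed under the block in the mutant (18 without it) and 15 across genotypes (14 without it), and the total was 58 list calls with the other comparisons unblocked and 54 with all blocked. The labels do not say that equal numbers share an animal or day, and deviations of equal-numbered mutant libraries correlated at 0.204. Under the block the TGF-beta list had an adjusted p of 0.0557 in the mutant. With all comparisons blocked, the interferon list in oxLDL-treated cells also lost its call. So did the sterol synthesis, actin and immediate early lists for genotype in untreated cells. The genotypes share only the number 1. No fit was possible without the 3 libraries that hold pancreatic transcripts, since no comparison keeps both arms. Depth limits the lowest level seen, as 3 counts correspond to 0.122 CPM in the deepest library and 0.263 CPM in the shallowest.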

Other observations

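The explanations for Ndufs5 and Ide were chosen after their values were seen, and the count over other groupings of the libraries was planned before. Xist, the transcript of the inactive X chromosome, had between 27695 and 47133 counts in each of the 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at most 3.

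Ndufs5 measured 19.97 and 18.1 CPM in the wild-type libraries and at most 0.448 CPM in the mutant ones. BC002163, a gene that shares sequence with Ndufs5, went the other way by a log2 fold change of 2.20 ± 0.13 (SE; edgeR adjusted p = 0.00543), from 5.12 and 6.02 CPM in wild type to between 24.3 and 26.8 CPM in the mutant. The hypothesis that reads were divided differently between near-identical copies predicts an equal sum, and the summed CPM differed between genotypes by at most 1.06-fold. A sequence difference between the genotypes that moves reads from 1 copy to the other would give such a sum. Both genotypes are labelled C57BL/6 and sequence reads were not analysed here, so that cause was not tested. Between genotypes across treatments, 1 of 16 genes known to differ between C57BL/6 substrains or related inbred strains was lower and none higher. The lower gene was Ide, described next. Their list did not pass (camera adjusted p = 0.123, and 0.734 with an estimated correlation). That test looks for a shift of the list in 1 direction, so it cannot exclude strain differences in single genes or in both directions.

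Ide was lower in the mutant by a log2 fold change of -0.89 ± 0.077 (adjusted p = 0.00986), and its neighbour Btaf1 by -0.62 ± 0.081 (adjusted p = 0.0238). The ratio of wild type to mutant was 1.88 for Ide in untreated and 1.83 in oxLDL-treated cells, and 1.60 and 1.48 for Btaf1. The hypothesis of a copy difference of 1 region that spans both genes predicts a similar decrease of the genes between them. Those genes had log2 fold changes of 0.23 ± 0.25 (Cpeb3), 0.023 ± 0.31 (A330032B11Rik) and 0.0054 ± 0.14 (March5), with a mean of 0.086 ± 0.14, which argues against 1 such region. Of 19 tested neighbours of Ide other than Btaf1, some of these genes among them, none passed, with a median log2 fold change of 0.062. Separate causes for Ide and Btaf1 were not tested, and DNA was not analysed here.

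Of 10 ways to split the 6 libraries into 3 and 3, the split by oxLDL gave 5134 calls and the highest other split 1 call. These 10 splits are too few for a share under 0.05. Besides the split, only genotype was in these fits, so in the other splits the oxLDL difference added to the spread and held calls down. The low counts of the other splits are therefore no check on chance.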
